A study of Rattus norvegicus with 2 samples.

How the data were processed

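Total RNA from rat C6 glioma cells, an established line grown in medium with serum, was extracted, converted to sense cDNA, fragmented, labelled with biotin by terminal transferase and hybridised to Affymetrix whole-transcript GeneChip arrays, per the labels' protocols. There were 2 arrays, 1 of undifferentiated C6 cells and 1 of cells treated with small molecules (SMiG), assigned by their titles. The compounds are given differently in the sample's labels (forskolin, rapamycin and I-BET151) and in the protocol text attached to both samples (20 µM CHIR99021 and 100 µM forskolin for 35 days), and no choice between them was made. The number of arrays limits the precision, and no test across samples was possible.

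The deposited table holds 1 value per probe set and array for 36685 probe sets. The values are taken to be log2 expression on a common scale made by the authors, as deposited, with the log base not given in the sources used here. The base was read from the values, which run from 1.26 to 13.09, above 11.09, the natural log of the highest value of a 16-bit scanner. The sorted values of the 2 columns differed by a median of 0.036, so the columns were already on a common scale, but the background correction and normalization are not given in the sources used here. The column medians were 4.84 (C6) and 4.86 (SMiG). No further normalization was applied, and how the authors combined probes into probe sets could change any fold.

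Gene names came from the platform annotation. Of the probe sets, 18511 had 1 gene symbol, 575 had several and 17599 had none, and genes were named only from the first kind. RefSeq names of the GRCr8 assembly were matched by gene number for 18394 probe sets, used for names only, and changed 0 symbols. Probe sets of 1 gene were averaged, which gave 18166 genes, 291 of them with several probe sets. In the 149 genes with exactly 2 detected probe sets, the differences of the pair had a median gap of 0.18 and an SD of the gap of 0.42 on the log2 scale.

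Olfactory and vomeronasal receptor genes, 1317 in all, were taken as silent. The floor of each array was the 95th percentile of their values, 4.82 for C6 and 4.93 for SMiG. A gene was detected if it lay above the floor on at least 1 array, as did 11018 genes, 78 of the silent ones among them (5.92%). Genes were counted as higher or lower at a log2 difference of 1, which is 2-fold, from the measured values. Among the counted genes, 28 of the higher were at or below the floor in C6 and 165 of the lower were at or below it in SMiG. For these the printed fold is the brighter value against the floor of the dimmer array, given as at least that fold.

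The 31 gene lists, on cell types, cell cycle, signalling targets of the named compounds, metabolism, stress, immunity, matrix, growth factors, histones and reference genes, were written before the data were examined. For each, the median log2 difference of detected members was placed among 10000 random lists of as many detected genes, drawn from 20 bins of mean expression. Some genes stand in more than 1 list. The rule for named genes was also set before the data were examined. It takes the 12 detected genes at each end of the difference, up to 4 members of each list with the largest absolute difference, and 25 genes named whatever their value. It leaves out symbols that start with LOC, RGD, AABR, Olr, Vom, Mir, Snor, Rn or Gm, which also removes ordinary genes whose symbols start with Rn or Gm, and names 153 genes. Of the genes named whatever their value, Glul, Hmgcs1 and Gapdh had no probe set with 1 symbol and were not analysed here. Genes named outside the rule are said to have been chosen after their values were seen.

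The procedure was tested on simulated data for 11018 genes with the spread of the silent genes. Genes changed 2-fold were counted in 54% of cases, 2.83-fold in 94% and 4-fold in 100%, against 0.176% of unchanged genes. Of lists of 25 genes, 2% of unchanged ones fell outside the central 95% of random lists, and 97% of those raised by 0.3 were found. That spread is technical and holds no variation between cultures. The differences of detected genes spread more widely, from −1.58 at the 2.5th percentile to 1.09 at the 97.5th. The 97% is therefore likely too high for real lists. Of the silent genes themselves, 0.683% passed 2-fold, more than the simulated 0.176%.

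The alternatives were a floor at the 99th percentile of the silent genes, no floor, centring on the median difference, removal of a lowess trend against mean signal (span 0.3), quantile normalization, the brightest probe set of each gene, each probe set alone, other fold thresholds, and random lists not matched on expression. Raising values below the floor to the floor was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Probe sets with several symbols were left out, and those with none were only counted.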

Results

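Gene expression was measured by microarray in the rat C6 glioma line, in 1 culture of undifferentiated cells (C6) and in 1 culture treated with small molecules (labelled SMiG). The series asks whether treated glioma cells take on the expression profile of glia and proliferate less. The labels disagree on the treatment. The sample's own labels name forskolin, an activator of adenylyl cyclase, with rapamycin, an inhibitor of mTORC1, and I-BET151, an inhibitor of BET bromodomain proteins. The protocol text attached to both samples names CHIR99021, an inhibitor of GSK3, at 20 µM and forskolin at 100 µM for 35 days. With 1 array per group there is no replicate error, no difference below has a replicate check, and no p-value is given. The number of arrays limits the precision. Of 18166 genes with a symbol, 11018 were detected, meaning that at least 1 array gave a signal above the level of olfactory and vomeronasal receptor genes. Where the dimmer array was at or below that level, the fold is given as a lower bound against it. Counts of genes past 2-fold use the measured values.

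Genes that were lower in SMiG outnumbered those that were higher. Of the detected genes, 713 (6.47%) were at least 2-fold lower in SMiG and 350 (3.18%) at least 2-fold higher, with 9955 within 2-fold. With values below the floor raised to the floor, the counts were 635 and 335. The imbalance was wider among large differences, with 143 genes at least 4-fold lower against 40 at least 4-fold higher. The median log2 difference of detected genes, SMiG minus C6 here and throughout, was −0.0018. Across detected genes the arrays correlated with a Pearson r of 0.911, where genes are not independent replicates. The 1317 receptor genes taken as silent had a log2 difference with an SD of 0.32, and 9 of them (0.683%) passed 2-fold.

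The gene with the largest excess in SMiG was Mgp, encoding matrix Gla protein, an inhibitor of calcification, at 11.52 against 5.33 in C6, a 73.0-fold difference. Cp, encoding the copper-carrying ferroxidase ceruloplasmin, was 10.8-fold higher, the creatine transporter gene Slc6a8 9.50-fold higher and Pmp2, encoding a lipid-binding protein of peripheral myelin, 8.67-fold higher. The receptor gene Lifr was at least 8.65-fold higher, Enpp2, encoding autotaxin, at least 7.33-fold, and the glial receptor gene Gpr37l1 at least 6.70-fold. Kank4, Masp1, Col18a1, Inka2 and Olfml2a completed the 12 highest, with folds from 7.48 for Kank4 to 6.35 for Olfml2a. At the other end, Serpinf1, encoding pigment epithelium-derived factor, was 38.0-fold lower and Spp1, encoding osteopontin, 29.5-fold lower. Scg2, encoding a protein of secretory granules, was below the floor in SMiG and at least 22.6-fold lower. The splicing factor gene Rbfox1 was at least 22.0-fold lower, Postn, encoding the matrix protein periostin, at least 19.8-fold, and the taurine transporter gene Slc6a6 at least 18.6-fold. Car9, encoding carbonic anhydrase 9, was 18.5-fold lower. The rest of the 12 lowest were Galnt3 (at least 17.3-fold), Nupr1 (at least 16.1-fold), Trib3 (at least 13.0-fold), Ano4 (at least 10.5-fold) and the cytokine gene Il33 (at least 6.20-fold). The ranks rest on measured values, and 9 of the 12 lowest genes were at or below the floor in SMiG, as were 3 of the 12 highest in C6, so their order is uncertain. Slc7a11, 13.6-fold lower, and Igfbp3, 12.1-fold lower, were above the floor on both arrays and exceed the bounds of Ano4 and Il33. Slc7a11 also exceeds the bound of Trib3.

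**Figure D1:**
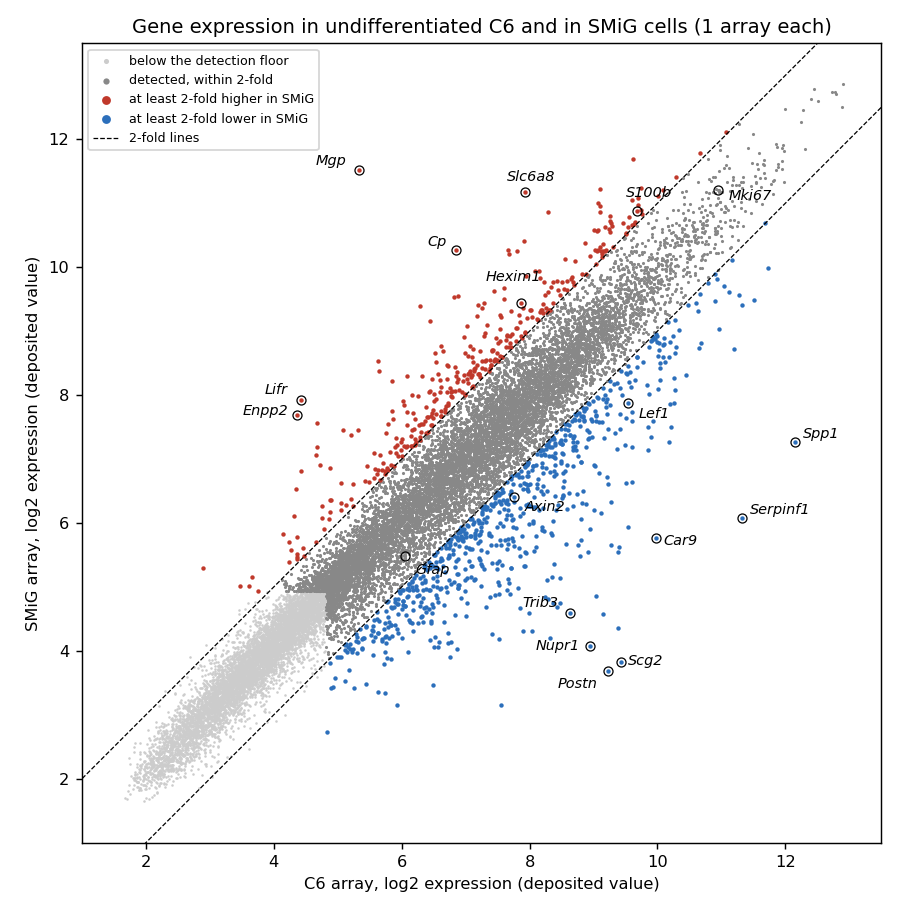
Log2 expression of each gene on the C6 array (x axis) and on the SMiG array (y axis), 1 array each, with dashed lines at 2-fold, grey points for genes within 2-fold or below the detection floor, red for genes at least 2-fold higher in SMiG and blue for genes at least 2-fold lower. The 713 blue points outnumber the 350 red ones, and Mgp lies farthest above the lines.

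To describe pathways and cell types, 31 gene lists fixed in advance were set against 10000 random lists of the same size and mean expression. The medians of 12 lists lay outside the central 95% of their random lists, 6 above and 6 below. By chance 1.55 would fall outside if the genes within each list varied as independently as randomly drawn genes. Genes of a list may vary together, so 1.55 is likely too low and 12 against 1.55 overstates the excess. A list's percentile describes these 2 arrays and does not test the treatment. A single value given for a gene is its log2 difference, and a pair of values gives its log2 levels. The mean had the opposite sign to the median in the stem cell, Schwann cell, unfolded protein response, interferon and BET-raised lists, each with members on both sides.

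**Figure D2:**
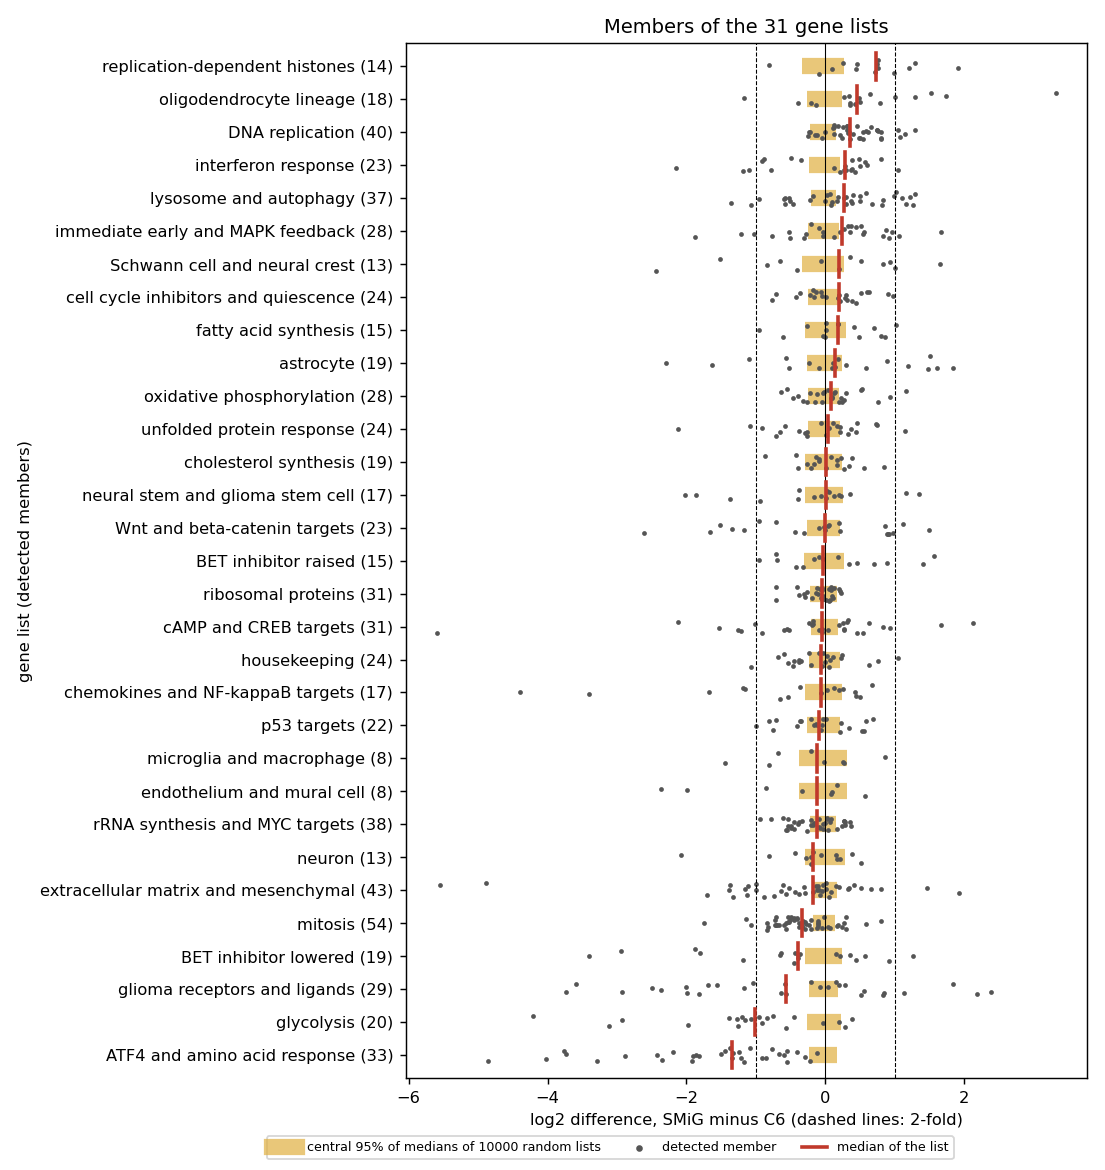
Log2 difference (SMiG minus C6, x axis) of each detected member of the 31 gene lists (y axis, number of detected members in brackets), with the list median in red and the central 95% of the medians of 10000 random lists in yellow. The ATF4 and amino acid list, with a median of −1.34, and the glycolysis list, with −1.01, lie farthest to the left.

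Genes of the amino acid response driven by the transcription factor ATF4 were lower in SMiG as a group. All 33 detected members of the list had a lower value in SMiG, 22 of them by at least 2-fold, and the median difference was −1.34, below each of the 10000 random lists. Slc7a11, encoding the cystine transporter subunit xCT, was 13.6-fold lower, at 5.63 against 9.39. Cth, encoding an enzyme of cysteine synthesis, was at least 11.3-fold lower, beside Nupr1 and Trib3 from the 12 lowest genes. Among genes named after their values were seen were Asns, encoding asparagine synthetase, at −2.42, the serine and folate enzyme genes Mthfd2 at −1.92 and Shmt2 at −1.91, and Atf4 itself at −0.59. The unfolded protein response list, which holds the chaperones of the endoplasmic reticulum, was not low as a group. Its median was 0.04, at percentile 71.2, with 2 of 24 members at least 2-fold lower and 1 at least 2-fold higher. Ero1a at −2.12, Herpud1 at −1.09 and Xbp1 at −0.90 were the lowest members, and Sdf2l1 was the highest at 1.16.

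The glycolysis list was also lower in SMiG. Of its 20 detected members, 10 were at least 2-fold lower and none at least 2-fold higher, with a median of −1.01, below each random list. With Egln3, named after its value was seen, at its bound of 1.74-fold, 9 were at least 2-fold lower. The glucose transporter genes Slc2a3 and Slc2a1 were 8.65-fold and 3.93-fold lower. The list also holds targets of hypoxia-inducible factors that are not glycolytic, among them Car9 and the angiogenic growth factor gene Vegfa, which was 7.58-fold lower at 7.26 against 10.18. Not each member was lower: among genes picked after their values were seen, Hk2 stood at −1.27 and Pdk1 at −1.25, whereas Ldha was at −0.03, Pfkl at 0.29 and Pfkm at 0.39. The oxidative phosphorylation list had a median of 0.09 (percentile 84.7), and Ndufa1 at 1.16 was its only member past 2-fold among 28.

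**Figure D3:**
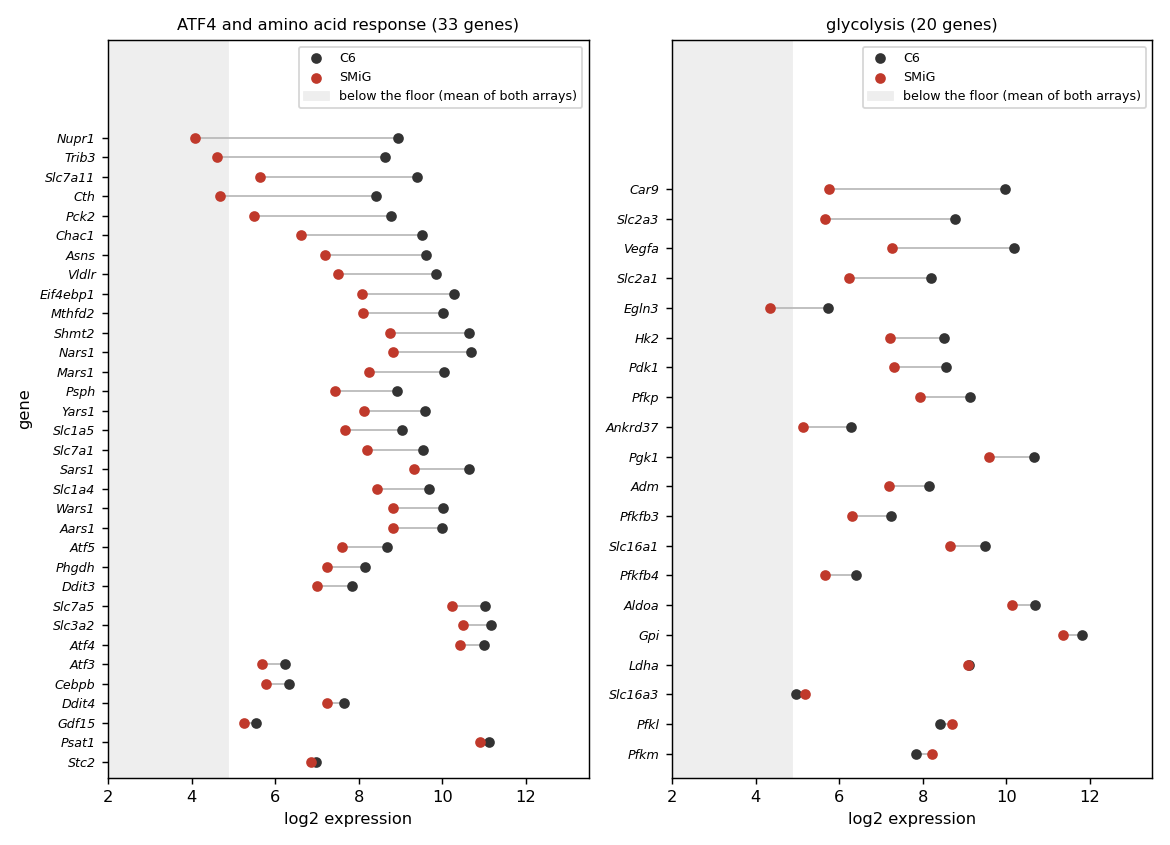
Log2 expression (x axis) of the detected members (y axis) of the ATF4 and amino acid list (left) and the glycolysis list (right) on the C6 array (black) and the SMiG array (red), with grey shading below the detection floor. Each of the 33 genes on the left is lower in SMiG, against 17 of 20 on the right.

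The lists of DNA replication genes and of mitosis genes had medians of opposite sign. DNA replication genes were higher in SMiG: 33 of 40 had a positive difference, 4 of them by at least 2-fold, and the median was 0.35 (percentile 99.99). The 4 were Ccne2, encoding cyclin E2, at 1.30, the replication licensing gene Cdc6 at 1.16, the chromatin assembly gene Chaf1a at 1.07 and Rrm2, encoding a ribonucleotide reductase subunit, at 1.05. Genes of mitosis were lower: 44 of 54 had a negative difference, 3 of them by at least 2-fold, and the median was −0.34, below each random list. Securin (Pttg1) stood at −1.75, the phosphatase gene Cdc25b at −1.13, the kinesin gene Kif18a at −1.07 and the kinetochore gene Ndc80 at −0.84. The proliferation marker Mki67 was at 11.21 in SMiG against 10.95 in C6, a difference of 0.27, and Top2a was at −0.30. Replication-dependent histone genes had the highest median of any list, 0.73 over 14 members with 3 at least 2-fold higher, H2ac20 at 1.91, H1f5 at 1.30 and H2bc8 at 1.21, with Hist1h4b at 0.99. Probe sets of such near-identical genes can share signal, so single histone genes are uncertain and the list's members may not be independent. Of 39 genes in the list, 18 had a probe set with 1 symbol, and 14 of these were detected.

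Genes that restrain the cell cycle gave small values. The list of cell cycle inhibitors and quiescence genes had a median of 0.19 (percentile 96.1) with none of 24 members past 2-fold, from Tob1 at 0.97 and Foxo1 at 0.90 to Gas2 at −0.77 and Cdkn1a at −0.71. Cdkn1b was at −0.05, Cdkn2a was below the floor on both arrays, and the cyclin gene Ccnd1 was at 0.21. The p53 target list had a median of −0.08 (percentile 26.9) and none of 22 members past 2-fold. Mdm2 came nearest, just inside the threshold at 7.87 against 8.87, followed by Gadd45a at −0.81 and Ddb2, at least 1.67-fold lower.

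Markers of the oligodendrocyte lineage were higher in SMiG, and markers of astrocytes were split. In the oligodendrocyte list 14 of 18 detected members had a positive difference, 5 by at least 2-fold against 1 lower, with a median of 0.46 (percentile 99.99). Those higher by at least 2-fold were Enpp2, Fa2h, encoding a fatty acid hydroxylase of myelin lipids, at 1.74, the myelin-associated enzyme gene Cnp at 1.52, Aspa at 1.30 and the lineage factor gene Sox10 at 1.01. The precursor markers Pdgfra at −1.17 and Cspg4 at 0.42, named after their values were seen, lay on opposite sides. With the floor at the 99th percentile of the receptor genes, 12 members were left and the median was 0.72. It was 0.35 with no floor and 0.35 with values below the floor raised to it. The myelin genes Mbp, Mog and Mag, also named afterwards, were at or below the floor in C6 and within 2-fold of it in SMiG. They were detected through SMiG alone, which favours a positive difference. In the astrocyte list 5 of 19 members were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.14 (percentile 87.1). Fgfr3 was 3.58-fold, Itpkb 3.05-fold and the calcium-binding protein gene S100b 2.30-fold higher, S100b at 10.87 against 9.67. The gap junction gene Gja1 was 4.92-fold and Ndrg2 3.08-fold lower. The other members past 2-fold, named after their values were seen, were Cst3 at 1.51, Clu at 1.49 and Chrdl1 at −1.09. Gfap, the intermediate filament gene of astrocytes, was at 5.48 in SMiG and 6.05 in C6, a difference of −0.56, while Aqp4 and Slc1a3 were below the floor on both arrays.

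The neural stem and glioma stem list had a median of 0.01 (percentile 53.6), with 2 of 17 members at least 2-fold higher and 3 at least 2-fold lower. The stem cell factor gene Sox2 was at 1.16 and Pou3f2 at 1.35, against Id3 at −2.02, the Notch target Hes1 at −1.86 and Klf4 at −1.38. Nes and Vim, encoding nestin and vimentin, were at −0.15 and 0.01, and Olig2 at 0.35. Lists of other cell types had few detected members and lay within the range of random lists. The neuron list had a median of −0.18 over 13 genes (percentile 8.57), with Gad1 4.24-fold lower, Eno2 at −0.81, Snap25 at 0.52 and Tubb3 below the floor on both arrays. The Schwann cell and neural crest list had a median of 0.19 over 13 genes (percentile 91.8), with Prx, encoding the myelin protein periaxin, at 1.65 against Cdh19, at least 3.47-fold lower, and Scn7a at −1.52. The microglia list had a median of −0.11 over 8 genes (percentile 18.8), with Cd14 at −1.44 and Tmem119 at −0.81. At the stricter floor Cd14 was the only member left. The endothelium and mural cell list had −0.12 over 8 genes (percentile 16.6), with Pdgfrb 5.15-fold and Flt1 at least 2.89-fold lower, the only 2 members left at the stricter floor. With no floor its median was 0.077 over 17 genes.

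Lists tied to the compounds named in the labels gave mixed readings. Genes that BET inhibitors commonly lower had a median of −0.39 over 19 members (percentile 0.46), with 5 at least 2-fold lower and 1 at least 2-fold higher. The chemokine gene Ccl2 was at least 9.96-fold lower, the heme oxygenase gene Hmox1 7.65-fold, Fosl1 3.68-fold and Has2 3.48-fold. The fifth, Il6, was below the floor in SMiG and has a bound of only 1.36-fold, so 4 are supported. The survival gene Bcl2, named after its value was seen, was 2.42-fold higher, and Myc was at 0.93. When genes below the floor were included, the median of this list was −0.070. Genes that BET inhibitors commonly raise had a median of −0.03 over 15 members (percentile 43.2). Hexim1, a common marker of BET inhibition, was 2.97-fold higher at 9.44 against 7.87, Serpini1 was at least 1.95-fold higher, Zcchc24 was at 0.89 and Sqstm1 at −0.95. The list of cAMP and CREB targets had a median of −0.044 over 31 members (percentile 30.0), with 2 at least 2-fold higher and 6 at least 2-fold lower. The clock gene Per1 was 4.37-fold higher and Junb 3.19-fold higher, whereas Gem was 4.34-fold lower, beside Scg2. Crem was at −0.19 and Nr4a1 at 0.94.

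The Wnt and beta-catenin list had a median of 0.00 over 23 members (percentile 54.3), with 2 at least 2-fold higher and 5 at least 2-fold lower. The feedback gene Axin2 was lower at 6.41 against 7.76 and Lef1, encoding a transcription factor of the pathway, was 3.16-fold lower. Nkd2 was 6.13-fold lower, Notum, counted among the 5, at least 1.77-fold lower, and Ephb2 2.83-fold higher. The other members past 2-fold, named after their values were seen, were the transcription factor genes Tcf7 at −1.17 and Tcf7l2 at 1.12. The immediate early and MAPK feedback list had a median of 0.24 over 28 members (percentile 98.99), with Junb and Ier2, at 1.06, at least 2-fold higher and Fosl1, Spred3 at −1.21 and Etv4, named after its value was seen, at −1.02 at least 2-fold lower.

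The lists of rRNA synthesis and MYC targets, ribosomal proteins, cholesterol synthesis and fatty acid synthesis had small medians. For rRNA synthesis and MYC targets the median was −0.12 over 38 genes (percentile 15.7), with none past 2-fold and Wdr43 at −0.94 and Gnl3 at −0.78 the lowest. Ribosomal proteins had a median of −0.04 over 31 genes (percentile 37.5), with Rpl6 and Rpl18 both at −0.70. Cholesterol synthesis had a median of 0.017 over 19 genes (percentile 63.0), from Hsd17b7 at 0.85 to Fdps at −0.87. Fatty acid synthesis had a median of 0.18 over 15 genes (percentile 89.2), with Acly, which makes cytosolic acetyl-CoA, at 1.02 and Me1 at −0.95. Lysosome and autophagy genes were higher in SMiG, with a median of 0.27 over 37 members (percentile 99.95), 6 at least 2-fold higher and 2 at least 2-fold lower. The cholesterol exporter gene Npc1 was at 1.29, the autophagy genes Gabarapl1 and Ulk1 at 1.27 and 1.23, and the cathepsin gene Ctsk, counted among the 2 lower, has a bound of only 1.63-fold. Gpnmb, named after its value was seen, was at −1.06.

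The list of growth factor signalling genes studied in glioma had a low median difference, with members on both sides. Of 29 detected members, 17 had a negative and 12 a positive difference, and the median was −0.57, below each random list. By at least 2-fold, 12 were lower in SMiG and 4 higher. Igfbp5 and Igfbp3, encoding binding proteins of insulin-like growth factors, were at least 11.7-fold and 12.1-fold lower, and the receptor gene Met was 5.63-fold lower, beside Vegfa and Pdgfrb. Among genes named after their values were seen, Pdgfc was 4.01-fold lower, and the ligand genes Igf1 and Tgfa were at least 3.98-fold and at least 3.29-fold higher and the receptor gene Igf1r 2.21-fold higher, beside Fgfr3. With genes below the floor included, the median of this list was −0.057. The extracellular matrix and mesenchymal list had a median of −0.18 over 43 members (percentile 1.97), with 9 at least 2-fold lower and 2 at least 2-fold higher. Against random lists not matched on expression it stood at percentile 2.84, inside the central 95%. Postn and Spp1 led it, Col6a2 was 3.27-fold lower, and Tgfb2 was 3.80-fold and Timp2, named after its value was seen, 2.77-fold higher.

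Of the immune lists, that of interferon lay above its random lists and that of chemokines and NF-kappaB targets lay inside them. The interferon list had a median of 0.29 over 23 members (percentile 99.7), 15 of them positive, B2m at 1.05 the only one past 2-fold upward, and Ifit2 at −2.15, Psmb8 at −1.09 and Usp18, at least 1.99-fold lower, at the other end. Chemokines and NF-kappaB targets had a median of −0.06 over 17 members (percentile 34.8), none at least 2-fold higher and 5 at least 2-fold lower. They were Il6, whose bound is only 1.36-fold, Il33, Ccl2, Irak3 at −1.68 and Lif, named after its value was seen, at −1.15. Housekeeping genes had a median of −0.06 over 24 members (percentile 31.1). Actb was at 0.08, while Pgk1, which the glycolysis list also holds, was 2.11-fold lower and B2m 2.06-fold higher.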

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

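No test in this part was planned before the data were seen. Probe sets without a gene name lie outside the comparisons of named genes, and part of them gave a signal and differed between the arrays. Of 17599 such probe sets, 7709 were above the floor on at least 1 array, and 9.42% of these differed by at least 2-fold, 288 higher in SMiG and 438 lower. The share is close to the 9.65% of named genes. The extremes were probe set 17681842, at 12.52 in SMiG against 8.16 in C6 (20.5-fold higher), and probe set 17882165, at 6.20 against 11.02 (28.4-fold lower). No explanation was tested for these probe sets.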

How the results depend on the processing

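One alternative, values below the floor raised to the floor, was chosen after the data were seen, and the others before. Counts and medians that answer a comparison stayed within their limits in 338 of their recomputed values and moved in 14. The 12 lists outside their random lists kept the sign of their median under every alternative, and medians of both signs were seen for the endothelium, BET-raised, cholesterol, chemokine and Wnt lists, whose medians lay near 0 or inside their random lists. Size was less stable than sign. The matrix median was −0.11 with no floor and −0.12 with values raised to the floor, inside the main bound of −0.17. The MAPK feedback median was 0.17 with the brightest probe set, inside the main bound of 0.19. Named genes kept their value within the spread of silent genes in 926 recomputed values of 926. Much of this was fixed in advance. The floor settings leave a gene's difference unchanged, centring shifts all genes by the same small amount, and few named genes have several probe sets. Raising values to the floor is not in this count, and it moved Il33 from −4.40 to −2.63 and Postn from −5.55 to −4.31. By construction, the fold threshold moved the counts most: 1145 genes higher and 1651 lower at 1.5-fold, 80 and 275 at 3-fold, and 40 and 143 at 4-fold. The share of lower genes among those counted was 67.1% at 2-fold and ran from 63.5% (quantile normalization) to 67.4% (brightest probe set) over the alternatives of scale, floor and probe set, against 59.0% at 1.5-fold and 78.1% at 4-fold. With the floor at the 99th percentile, which drops dim members, the list medians became 0.72 for the oligodendrocyte lineage (12 members) and −0.28 for extracellular matrix (36 members). For microglia only Cd14 was left, at −1.44, and for endothelium and mural cells only Pdgfrb and Flt1, with a mean of −2.18, so neither describes its list. With no floor, which adds silent members, they were 0.077 for endothelium and mural cells, −0.070 for genes lowered by BET inhibitors and −0.057 for glioma receptors and ligands. Against unmatched random lists the matrix list stood at percentile 2.84, and the cause was not tested. Signal near the floor limits folds to lower bounds, and no leave-one-out was possible with 1 array per group.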

Other observations

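The tests on the further cytosolic synthetases, the further hypoxia targets, the further S phase genes and the further mitosis genes had their prediction written before their result was seen, and the other tests in this part were chosen only after it. The further synthetases were 6 cytosolic aminoacyl-tRNA synthetases outside the ATF4 list, chosen because they are known ATF4 targets. Their median log2 difference was −1.52, below each of 10000 matched random lists, with 6 of 6 lower in SMiG and 5 of them by at least 2-fold. Cytosolic synthetases that are not known ATF4 targets were not scored as a set, so compartment and ATF4 control cannot be told apart. The 15 detected mitochondrial synthetases had a median of −0.12 (percentile 21.4), with 8 lower and 7 higher.

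The ATF4 and amino acid genes were the lowest list in SMiG. A trend of the difference with signal strength is argued against as the whole cause, since random lists matched on mean expression share such a trend and the median of −1.34 lay below each of them. A lowess correction moved too little to test it. Lower output of the ATF4 programme is a candidate explanation, and the median of −1.52 in the 6 further synthetases is what it predicted. These 6 are known ATF4 targets, read on the same 2 arrays as the list. The result therefore extends the pattern to more ATF4 targets and does not tell its cause. A general loss of mTORC1 output that includes SREBP targets predicted a low cholesterol synthesis list, and its median of 0.017 (percentile 63.0) was not low. The list was not clearly raised either, and with 1 array per group this explanation cannot be excluded. Culture conditions such as medium age or density were not tested, and with 1 culture per group they cannot be separated from the treatment.

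Lower output of hypoxia-inducible factors is a candidate explanation for the low glycolysis list. In 20 further hypoxia targets outside that list the median was −0.34 (percentile 0.96), with 15 lower in SMiG and 5 higher. The shift was smaller than the −1.01 of the glycolysis list, and 1 of the 20 passed 2-fold. The glycolysis list itself holds hypoxia targets, and both sets were read on the same arrays. The result therefore extends the pattern to more hypoxia targets and does not tell its cause. Oxygen supply and cell density may differ between 2 cultures and were not tested.

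The direction of Axin2 and Lef1 bears on which compounds were used, since a GSK3 inhibitor turns on Wnt targets. Axin2 stood at −1.34, opposite to what CHIR99021 in the SMiG culture would predict, but the Wnt list as a whole was centred on 0.00 and the spread of silent genes holds no variation between cultures, so the protocol text cannot be excluded. A swap of the arrays, with the compounds of the sample's own labels, would raise the genes that BET inhibitors lower in the array labelled SMiG. These had a median of −0.39. Hexim1, which BET inhibitors raise, was higher at 1.57 in the array labelled SMiG, but the list of genes they raise had a median of −0.03, and Myc at 0.93 and Bcl2 at 1.27 went against the lowered list. The median of the lowered list kept its sign but went to −0.070 without the floor, so the BET lists leave a swap open. Readouts of rapamycin were not tested for it. For a swap with the compounds of the protocol text, Wnt targets and cAMP and CREB targets would be lower in the array labelled SMiG. Axin2 and Lef1, at −1.66, lay in that direction. The Wnt list was centred on 0.00, with 5 members at least 2-fold lower and 2 at least 2-fold higher, so this swap stays open. The cAMP and CREB median of −0.044, over members on both sides, decides nothing. Forskolin is named in both sets of compounds, so the cAMP reading applies to either swap.

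Higher DNA replication genes beside lower mitosis genes might reflect a shift of cells between phases. A trend with signal strength is argued against as the whole cause, since random lists matched on mean expression share it, and the replication median of 0.35 (percentile 99.99) and the mitosis median of −0.34 (below each) lay outside them. A larger share of cells in S phase stays open, as 22 further S phase genes had a median of 0.19 (percentile 95.6), inside the central 95% of random lists, with 17 of 22 higher. A smaller share in G2 and mitosis also stays open, as 20 further mitosis genes had a median of −0.30 (percentile 2.52), just inside the central 95%. Phase shares were not measured, and no biological explanation can be told from differences between 2 cultures.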
